A study of Taeniopygia guttata with 54 samples.

How the data were processed

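RNA from 54 tissue punches of 27 adult male zebra finches, 1 of area X and 1 of VSP per bird, had been hybridised to 54 1-colour arrays on 14 slides. Each array held 43803 spots that were not controls, with 42994 distinct probes of 60 nucleotides. Per the file headers and the submitters' processing notes, the authors extracted the spot intensities with Agilent Feature Extraction 9.5.3.1. Per the file headers, the deposited processed intensity of a spot is its mean brightness after background subtraction and removal of spatial trends, with low values replaced by a surrogate, and nothing had been normalized between arrays. The 92 scanner and extraction settings compared were the same in all files. The flags of a spot (well above background, saturated, outlier) were used as the authors deposited them. The authors' own table of processed values holds a linear intensity for the 51 arrays of their final set. How it was scaled is not given in the sources used here, its row numbers match no probe, and its quartiles were nearly equal within a region and different between regions. It therefore served as an alternative without gene names and not for the comparison of regions.

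Spots with an outlier flag were left out, replicate spots of a probe were averaged (101 probes lay on more than 1 spot), and log2 of the processed intensity was taken relative to the 75th percentile of each array. A probe was tested when it was well above background on at least 0.5 of the arrays of a group compared. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. Area X was compared with VSP over the 25 birds with both arrays in the final set, with the bird as a fixed block. Singers and non-singers were compared in each region alone. The difference of the singing effect between the regions was tested as an interaction with the bird as a block. Slopes on motifs, per 500 motifs, and on 4 acoustic features, per SD, were fitted within the 18 singers. The block rests on the labels, which give both punches the number of the bird they came from. The deviations of the 2 arrays of a bird from their group means correlated with a median r of 0.765 (0.622 to 0.833), and in 25 of 25 birds each area X array was closest to the VSP array of the same bird. No pair of arrays held identical values, and their correlations lay between 0.928 and 0.988.

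Gene names came from the files and from a table of 23294 zebra finch genes. Of the accessions and names in the array design, 12 probes matched by accession and 6 by synonym, which gave 7 symbols, and 13 further probes kept the readable name of the design. The remaining probes are named by clone or unmatched accession and their genes are not named here. A gene with several probes was represented by its brightest probe. Named in each comparison were to be the 12 genes with the largest positive and the 12 with the largest negative change among those that passed, up to 4 members of each fixed gene list, and EGR1, FOS, ARC and FOXP2. With 20 named genes this rule took in all that were measured; FOS, ARC and FOXP2 have no named probe. Of 22 gene lists fixed before the data were examined, 17 had no member whose symbol was found, as written, among the names of the probes: those of heat shock proteins, medium spiny neurons, pallial excitatory neurons, astrocytes, oligodendrocytes, microglia, vascular cells, red blood cells, ependymal cells, glutamate, GABA and neuromodulator receptors, potassium channels, MAP kinase, oxidative phosphorylation, ribosomal proteins and proteasome. The lists of activity-regulated genes (EGR1), FOXP and Reelin genes (Robo1), interneuron markers (ER81), steroid receptors (ESR1) and axon guidance genes (Robo1, Robo2, Slit3) had 1 to 3, fewer than the 5 needed for a test of the list. With the design names D1a, D1b, D2R, D2_long, D3, EphrinA5 and ROR_Beta read as listed genes, the neuromodulator receptors had 4 members (3 measured), the axon guidance genes 4, the medium spiny neuron markers 2 and the pallial markers 1 (too dim to be tested), which was still too few; D1D_like and MTNR1A were not on a list. Unnamed probes are given by identifier and sequence. Where an unnamed probe or MTNR1A was not well above background on every array of the dimmer group, the fold is a lower bound, with each array of that group set to the higher of its own signal and the lowest signal among the probes well above background on that array. These bounds were computed with the deposited background subtraction alone.

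The network used the 5000 probes of highest variance over the area X arrays, a signed adjacency to the power of 12, topological overlap, average linkage, and the height (0.59, from 0.5 to 0.99 in steps of 0.01) that gave most modules of at least 30 probes. Group differences of an eigengene or of EGR1 were tested by exact two-sided permutation in place of the planned 100000 resamples, which were kept for correlations. The difference of an eigengene between regions was scored over both regions together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

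The fits were tested on simulated arrays drawn from the real means and spreads with 200 probes changed by known amounts. Probes were drawn independently, with spreads averaged over the groups and no slide component. The simulated arrays of a bird shared 0.5 of the variance, while the correlation estimated within real birds was 0.697. The shares recovered by fits with the bird as a block may therefore not hold for the real arrays. For singers against non-singers in area X, 46.3% of changes of 0.5, 74.6% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered among 40582 probes, with 2 false calls. For the region comparison 82.1%, 100% and 100% were recovered among 40860 probes. For the interaction 37.3%, 83.6% and 97.0% were recovered among 40860 probes, and for motif slopes in area X 49.3%, 94.0% and 98.5% among 40244 probes. Of 220 simulated module probes in 3 planted modules among 1000 probes, 185 were recovered in 3 modules.

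The first principal component of the deviations from the region means held 26.8% of the variance and split the slides into set A (9 slides) and set B (5 slides, 9 birds). In area X set B held 7 singers and 2 non-singers. Slides 1 to 9 held a non-singer at positions 1 and 2 and a singer at positions 3 and 4. Slides 10 to 13 held a singer with few motifs (134 to 182) at positions 1 and 2, and slide 14 held 1 singer.

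Alternatives chosen before the data were examined were normexp background correction with an offset of 50 fitted on all spots, quantile normalization, the authors' own table, no filter and a stricter filter on background, outlier spots kept, eBayes with trend and robust options, the 3 excluded arrays put back, the block left out, the slide as a block, age as a covariate, singers with many or few motifs, other scales of motifs, and each bird left out in turn. For the network they were another power, 3000 probes, singers alone, quantile normalization and the authors' table. The motif slopes of each region at positions 3 and 4 alone were also planned. The other position subsets and the slide set as a covariate were added after the data were seen.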

Results

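RNA was measured in 2 parts of the basal ganglia of 27 adult male zebra finches, which had sung different amounts of song during 2 h in the morning. Area X is the striatal nucleus of the song system, and the ventral striato-pallidum (VSP) lies beside it. Each bird gave 1 tissue punch of each region and each punch went on its own 1-colour array of 60-nucleotide probes, so that the bird was the replicate. A total of 18 birds sang freely and produced between 134 and 1270 motifs, a motif being the stereotyped song phrase of a bird. The other 9 birds were kept from singing by a person nearby and counted as non-singers because they sang fewer than 10 motifs (0 to 4 in those compared here). The effect of singing below is the difference between these groups, so singing cannot be told apart from the presence of that person. The submitters' labels set 3 arrays of non-singers apart, 1 of area X and 2 of VSP. The comparisons below used the other 51 arrays: 18 singers and 8 non-singers in area X, and 18 singers and 7 non-singers in VSP, with 25 birds measured in both regions.

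On average 93.0% of spots were well above background on the area X arrays of singers, 93.3% on those of non-singers, 93.1% on the VSP arrays of singers and 93.8% on those of non-singers. The number of arrays limits the precision of the values. Of 42994 distinct probes, 42821 carried a clone name and no gene. Gene names could be given to 31 probes: 18 matched 7 gene symbols and 13 had a readable name from the design of the array. Levels are log2 signals relative to the 75th percentile of the array, so that a level of 0 is that of a bright probe. Probe counts are not gene counts, because several probes can report on 1 transcript.

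The first comparison asked how the song nucleus differs from the neighbouring VSP of the same bird. The measured probes named for dopamine receptors were higher in area X, and that of D3 was too dim to be tested. D2R was higher by 1.09 on the log2 scale (SE 0.08, 2.13-fold, adjusted p = 2.26e-12) in 25 of 25 birds, and its level in singers was −1.21 ± 0.57 (SD, n = 18) in area X and −2.24 ± 0.53 (SD, n = 18) in VSP. D2_long was higher by 0.97 (SE 0.09) and D1b by 0.97 (SE 0.09), each in 25 of 25 birds. D1a was higher by 0.52 (SE 0.06) and D1D_like by 0.28 (SE 0.05). The axon guidance receptors Robo2 and Robo1 went opposite ways: Robo2 was higher in area X by 1.00 (SE 0.09, adjusted p = 6.97e-11, 24 of 25 birds) while Robo1 was −0.74 (SE 0.07, adjusted p = 2.79e-10, 24 of 25 birds). Among the genes lower in area X were the transcription factor CREB1 at −0.64 (SE 0.05) and the axon guidance ligand EphrinA5 at −0.59 (SE 0.07). The melatonin receptor MTNR1A was at least 2.01-fold lower in area X (limma adjusted p = 3.23e-09), a lower bound because 12 of 18 singers and 6 of 8 non-singers had it well above background there. That bound holds for the deposited background subtraction only, since with normexp the difference was −0.093 on the log2 scale.

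FNDC9 was higher in area X by 0.52 (SE 0.14) and LARP5 by 0.19 (SE 0.05), and the oestrogen receptor ESR1 at −0.43 (SE 0.10), SCAMP1 at −0.17 (SE 0.03) and Slit3, a ligand of the Robo receptors, at −0.15 (SE 0.05) were lower. In all, 15 of the 17 named genes measured differed, 8 higher and 7 lower in area X, with D2R and D2_long, which may be forms of 1 gene, counted apart here and below. The exceptions were the transcription factor ER81 (0.05, SE 0.03, adjusted p = 0.195) and the immediate early gene EGR1 (0.42, SE 0.29, adjusted p = 0.198), which was higher in area X in singers alone (1.17, adjusted p = 5.59e-05) and lower in non-singers alone (−1.52, adjusted p = 0.000329). The probes of D3, NR5A1 and ROR_Beta were too dim in every group to be tested. Across the array 28523 of 40860 probes differed between the regions (limma with the bird as a block, Benjamini-Hochberg adjusted p under 0.05), 14235 higher and 14288 lower in area X. Most differences were small, with a median size of 0.31, and 760 probes were higher and 1461 lower by at least 1 on the log2 scale. The unnamed probe 0203P0072M14 (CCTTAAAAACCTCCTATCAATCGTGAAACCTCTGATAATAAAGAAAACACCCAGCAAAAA) was at least 176-fold higher in area X (adjusted p = 5.53e-18), a lower bound because it was well above background on 1 of 18 VSP arrays of singers and 3 of 7 of non-singers. In the other direction, 0206P0023D06 (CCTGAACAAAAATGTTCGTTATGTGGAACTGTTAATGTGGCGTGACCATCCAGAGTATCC) was at least 46.0-fold lower in area X (adjusted p = 2.55e-16), where 13 of 18 singers and 4 of 8 non-singers had it well above background. Region and place on the slide went together in every bird (area X at positions 1 and 3, VSP at 2 and 4), so that the place could not be separated from the region. With another background correction (normexp) 18658 probes differed, ESR1 and Slit3 turned to 0.0696 and 0.10, and 5 more named genes no longer passed. These were MTNR1A (−0.093, SE 0.26), CREB1 (−0.15, SE 0.16), Robo1 (−0.28, SE 0.16) and EphrinA5 (−0.25, SE 0.15), all smaller in size and with wider errors, and LARP5 (0.32, SE 0.18), larger in size and with a wider error. In non-singers alone FNDC9 was 0.11 (adjusted p = 0.672), ESR1 −0.15 (adjusted p = 0.213) and Slit3 −0.079 (adjusted p = 0.444). Among the birds at positions 1 and 2 FNDC9 was 0.26 (adjusted p = 0.195), LARP5 0.20 (adjusted p = 0.0588), ESR1 −0.30 (adjusted p = 0.0966) and Slit3 −0.080 (adjusted p = 0.422). Without the bird as a block LARP5 (adjusted p = 0.178) and Slit3 (adjusted p = 0.424) did not pass, and with quantile normalization Slit3 did not (adjusted p = 0.0676) while ER81 did (0.091, adjusted p = 0.00756).

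**Figure D1:**
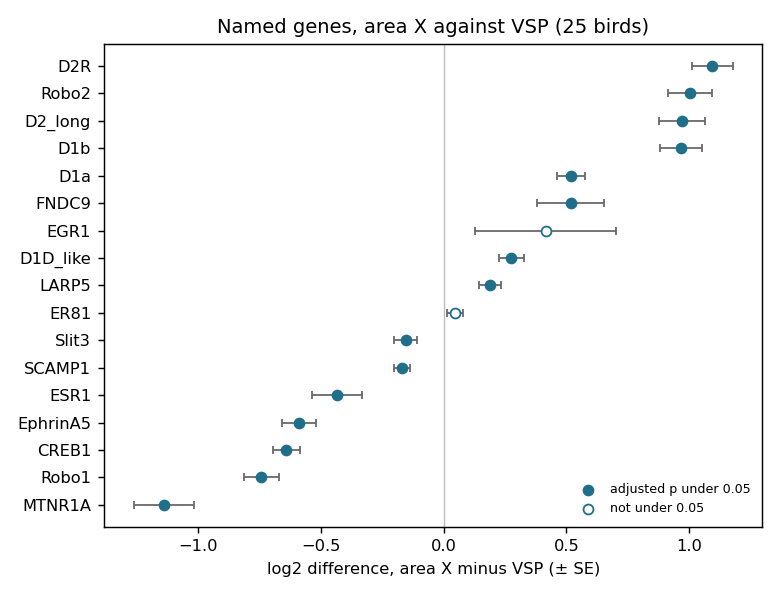
Log2 difference between area X and VSP within 25 birds for the 17 named genes measured (points, with the standard error as bars, filled where the adjusted p was under 0.05). Dopamine receptor probes and Robo2 lie to the right, from 0.28 for D1D_like to 1.09 for D2R, and CREB1 lies to the left at −0.64; the point of MTNR1A (−1.14) is limited by background in area X and was −0.093 with normexp, and ESR1 and Slit3 changed sign with normexp.

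Singing was compared next, first in area X. EGR1, a transcription factor gene that active neurons switch on within minutes, was higher in singers by 2.83 on the log2 scale (SE 0.33, 7.10-fold, limma adjusted p = 5.09e-06). Its level was 1.17 ± 0.93 (SD, n = 18) in singers and −1.66 ± 0.38 (SD, n = 8) in non-singers. Every singer compared lay above every non-singer compared. The area X array of a non-singer outside the final set was at 0.73, above 3 singers, and why it was left out is not given in the sources used here. In an exact two-sided permutation test the p was 6.4e-07, the smallest that its 1562275 splits can give. All 12 EGR1 probes rose, by 2.76 to 2.90. Several of them have the same or overlapping sequences, so their agreement is not independent evidence. On each of the 8 slides that held a singer and a non-singer the singer had more EGR1, by 1.01 to 4.05 (mean 3.02 ± 0.91 SD, n = 8, exact permutation p = 0.00781, the smallest possible). The singer was at position 3 and the non-singer at position 1 on each of them, and on the 4 slides with 2 singers the bird at position 3 exceeded the other by 0.78 ± 1.24 (SD, n = 4). On these 4 slides the bird at position 3 had also sung more motifs. The slides fell into 2 sets, A and B, by the first principal component. Within them the difference was 2.96 in set A (11 singers, 6 non-singers, exact permutation p = 8.08e-05) and 2.78 in set B (7 singers, 2 non-singers, exact permutation p = 0.0278), the smallest p possible in each. EGR1 was the 1 member of the list of activity-regulated genes that had a named probe, and the other 16 named genes measured did not pass.

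Across the array 2105 of 40582 probes differed between singers and non-singers in area X, 1185 higher and 920 lower in singers. The rises were the larger changes: 171 probes rose and 25 fell by at least 1, and 51 rose and 1 fell by at least 2 on the log2 scale. The 12 EGR1 probes are among the 51. The unnamed probe 0064P0014C11 (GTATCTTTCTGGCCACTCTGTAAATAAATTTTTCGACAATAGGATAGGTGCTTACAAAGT) rose by 3.45 (SE 0.35, adjusted p = 4.05e-06) and 0202P0017P02 (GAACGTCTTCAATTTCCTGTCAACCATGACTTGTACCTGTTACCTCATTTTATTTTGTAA) by 3.31 (SE 0.47, adjusted p = 7.99e-05). Of those that fell, 0203P0055P12 changed by −1.77 (SE 0.50), and 0206P0028K08 was at least 4.35-fold lower in singers (adjusted p = 0.00892), of which 8 of 18 had it well above background. With the slide as a fixed block 1874 probes differed, with the slide as a random block 3077, and with normexp 684. Singers with at least 500 motifs differed from non-singers at 3701 probes, while the 6 singers with fewer differed at 0 probes by limma (3647 at an unadjusted p under 0.05), with EGR1 at 2.25 (SE 0.47, adjusted p = 0.138). Most singers with fewer motifs were at position 1, as were all non-singers, and most of the others at position 3. Position and group size (6 against 12 singers) therefore went with the amount of song here, and their parts were not separated.

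In VSP no probe passed between singers and non-singers. EGR1 was 0.00 ± 0.51 (SD, n = 18) in singers and −0.20 ± 0.76 (SD, n = 7) in non-singers, a difference of 0.20 (SE 0.25, limma adjusted p = 0.997, exact permutation p = 0.458), with the singer higher on 4 of the 7 slides that held both. None of the 17 named genes passed. By limma 0 of 40637 probes differed, and 1470 had an unadjusted p under 0.05, which is 3.62% of the probes tested. In simulated data with the same number of arrays this fit found 40.3% of probes changed by 0.5 on the log2 scale. It found 83.6% of those changed by 1 and 98.5% of those changed by 2. The simulated probes were independent, with spreads averaged over the groups of both regions and no slide component. These shares may therefore not hold for the real arrays.

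The difference between the regions was then tested directly, as the area X minus VSP difference within a bird compared between singers and non-singers. For EGR1 the effect of singing was larger in area X by 2.69 (SE 0.38, limma adjusted p = 6.98e-05). Within birds, EGR1 was higher in area X than in VSP in 17 of 18 singers, by 1.17 ± 0.96 (SD, n = 18) on average, and lower in area X in 7 of 7 non-singers, where the difference was −1.52 ± 0.65 (SD, n = 7). All 12 EGR1 probes passed, and none of the other 16 named genes did. In all, 5453 of 40860 probes had a singing effect that differed between the regions, 2039 with a more positive and 3414 with a more negative effect in area X. Of the 5432 of these tested in both regions, 82.1% had the larger effect in area X and 64.0% had effects of opposite sign in the regions. These probes were selected for a difference between the regions; of all 40320 probes tested in both regions 61.5% had effects of the same sign, as did 65.9% of those called in area X. A total of 3780 were not called between singers and non-singers in area X. A total of 1673 of the 2105 probes called in area X also passed this test in the same direction; both tests use the same area X arrays. The unnamed probe 0202P0017P02 led with 4.09 (SE 0.47), followed by 0065P0027D05 with 3.77 (SE 0.45). The number and the direction of these calls moved with the processing: the share with a more positive effect in area X was 37.4%, and 50.3% of 1226 calls with normexp, 54.0% of 4994 with quantile normalization and 64.0% of 3693 in the authors' own table. With the slide as a block on the difference within birds 1114 probes passed, and without the bird as a block 436. Place on the slide was not separated from singing here: non-singers were at positions 1 and 2, and 13 of the 18 singers at positions 3 and 4. No subset by position was fitted for this difference.

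**Figure D2:**
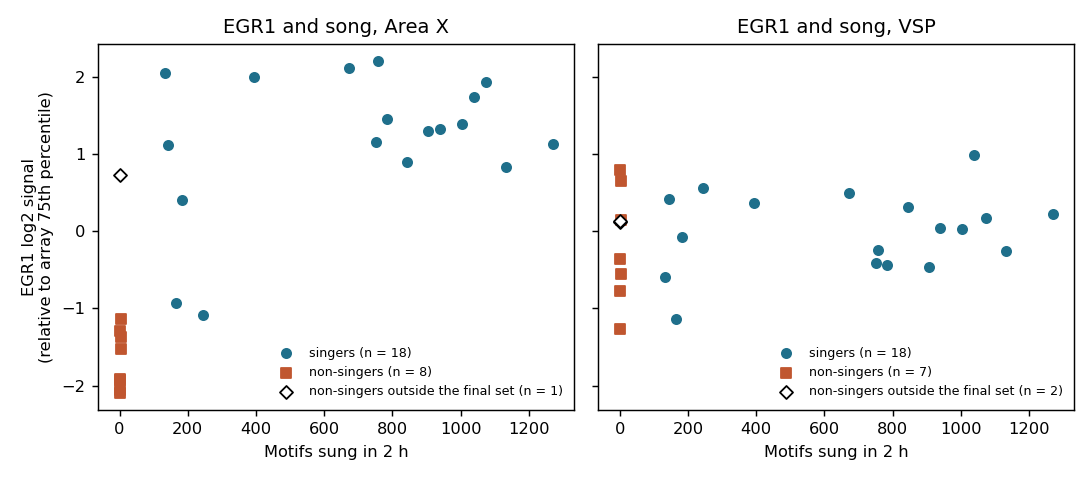
EGR1 log2 signal of each array (vertical axis, relative to the 75th percentile of the array) against the motifs the bird sang in 2 h (horizontal axis), in area X on the left and VSP on the right; circles are singers, filled squares non-singers and open diamonds the non-singer arrays outside the final set. In area X the singers lie between −1.09 and 2.21 and the 8 non-singers at or below −1.13, and in VSP both groups overlap.

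The amount of song was examined within the 18 singers, since singers and non-singers form separate clusters of motif number. EGR1 had a slope of 0.46 per 500 motifs in area X (SE 0.27, limma adjusted p = 0.614) and of 0.14 in VSP (SE 0.15, adjusted p = 1.00). The slope in area X was 0.25 without bird 11 and 0.65 without bird 22, and that in VSP was 0.013 without bird 11 and 0.22 without bird 16, the lowest and highest with 1 bird left out. Pearson's r between EGR1 and motifs in area X was 0.376 (permutation p = 0.124, adjusted p over both regions = 0.247) and Spearman's rho was 0.0857 (permutation p = 0.734). Without the 2 birds farthest from the median number of motifs r was 0.560, and it was 0.392 in the 13 singers on position 3. The 2 birds left out were those with the fewest motifs (134 and 143), and their EGR1 was 2.05 and 1.12. In VSP r was 0.209 (permutation p = 0.405) and rho 0.135 (permutation p = 0.595). Within slide sets, r was 0.256 in set A and 0.551 in set B in area X, and 0.558 and −0.361 in VSP. EGR1 in area X was 0.59 ± 1.38 (SD, n = 6) in singers with fewer than 500 motifs and 1.45 ± 0.45 (SD, n = 12) in the others.

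Of 40244 probes tested for a motif slope in area X, 1 passed, the unnamed probe 0203P0020P11 at −0.47 per 500 motifs (SE 0.06, limma adjusted p = 0.0322), and 4049 had an unadjusted p under 0.05. With 1 bird left out the count was 0 for 11 of the 18 birds and at most 51 (without bird 5). In VSP 0 of 40271 passed by limma (1159 unadjusted). For the difference of slopes between the regions 0 of 40574 passed by limma (5756 unadjusted). These counts moved with several choices. Against log2 of the motifs 280 probes passed in area X and 823 for the difference between the regions, and against their rank 0 passed in area X (3247 unadjusted). With the slide as a random block 1048 passed in area X, with trend and robust variance 64, and 53 in the authors' own table. Of 2100 probes called between singers and non-singers in area X and tested here, 87.6% had a motif slope in the direction of the singing effect, against 59.2% of all probes. Among the 13 singers on position 3 it was 67.3% of 2096 probes, a share that 12 of 100 orders of the motif numbers reached, the real one included.

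The labels also give each singer's mean pitch, frequency modulation, Wiener entropy and pitch goodness, which describe the sound of the song. Each was tested in both regions, 8 comparisons in all, and 0 probes passed in any of them by limma, with between 1207 and 4003 at an unadjusted p under 0.05. CREB1 in area X had the smallest p of a named gene, with a slope of −0.35 per SD of mean pitch (SE 0.10, unadjusted p = 0.00207, adjusted p = 0.575).

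The series is about co-expression, so a signed network was built from the 5000 most variable probes in area X. It gave 3 modules with 610, 48 and 31 probes. Module 2 held all 12 EGR1 probes, whose correlation with the module's eigengene (its first principal component) was 0.988 to 0.993, and all 48 of its probes were higher in singers, by a median of 2.82. Its eigengene was 0.58 ± 0.56 (SD, n = 18) in singers and −1.30 ± 0.17 (SD, n = 8) in non-singers, a difference of 1.87 (exact permutation p = 6.4e-07, the smallest possible, adjusted over 3 modules 1.92e-06), and it was higher in the singer, at position 3, on 8 of 8 slides. Because EGR1 probes make up 12 of the 48, the module is not independent evidence about EGR1. In VSP the same probes gave a difference of 0.19 (exact permutation p = 0.676), and the difference between the regions was 2.40 (permutation p = 6.24e-06, adjusted 1.87e-05). The module was built on area X arrays alone, which favours a larger difference there.

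The eigengene of module 2 had r = 0.437 with motifs among singers in area X (permutation p = 0.0700, adjusted p = 0.210) and rho = 0.129 (permutation p = 0.608). Without the 2 birds with the fewest motifs, which lay farthest from the median, r was 0.565. In the 13 singers on position 3 it was 0.292, and within slide sets it was 0.281 in set A and 0.730 in set B. None of the 3 modules passed for r with motifs in area X, but in other networks some did: 1 of 5 modules in a network of singers alone, 2 of 7 in the authors' own table and 3 of 19 with slide set means removed. For rho, 0 passed in any network. Modules 1 and 3 followed the slides: 98.7% and 97.5% of their variance in area X lay between slides. They did not differ between singers and non-singers in area X (differences 0.15 and 0.10, exact permutation p = 0.726 and 0.829). In VSP module 1 was higher in the singer on 7 of 7 slides, by 0.25 ± 0.13 (SD, n = 7, exact permutation p = 0.0156, adjusted p = 0.0469), although over all VSP arrays the difference was 0.39 (exact permutation p = 0.390). On those slides the singer was always at position 4 and the non-singer at position 2. On the 4 slides with 2 singers module 1 was also higher at position 4 on 4 of 4, by 0.16 to 0.26. The bird at position 4 had also sung more motifs on these slides (940 to 1270, against 134 to 182). The difference in module 1 therefore went with the position, but position was not separated from the amount of song.

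**Figure D3:**
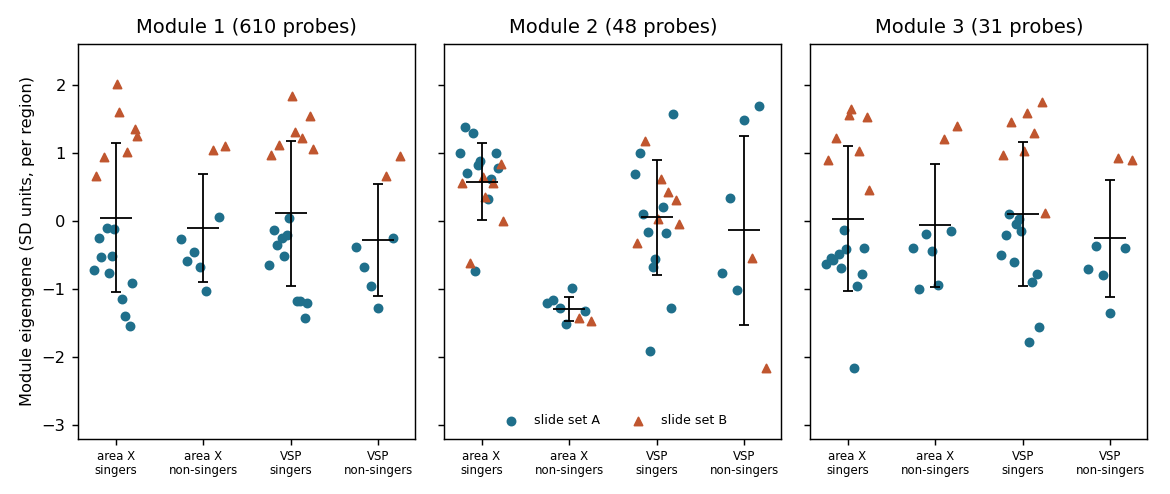
Eigengene of the 3 modules (in SD units within a region) on each array of the final set, by region and singing group; bars give mean and SD, and circles and triangles are arrays of slide sets A and B. Module 2 separates singers (mean 0.58) from non-singers (mean −1.30) in area X, and modules 1 and 3 separate the slide sets.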

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

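The splits by group and by region and the test of motif slopes on position 3 were planned before their results were seen; the tests of slide, of position in the singing comparison, of motif order over all singers, of singing group and brightness behind the slide sets, and of EGR1 in arrays outside the final set were chosen after. Those of singing group and brightness replaced earlier versions that gave p-values alone and whose results had been seen.

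EGR1 was higher in singers than in non-singers in area X and not detectably so in VSP. The test of the difference itself gave 2.69 on the log2 scale (limma adjusted p = 6.98e-05). The eigengene of module 2 gave 2.40 in SD units (adjusted permutation p = 1.87e-05). That is not independent support, since the module was built in area X and holds the EGR1 probes. In all 5453 probes passed the limma test of the difference between the regions. Of these 3780 were not called in area X and 64.0% had effects of opposite sign in the regions. Effects had the same sign for 65.9% of the probes called in area X, against 61.5% of all 40320 probes tested in both regions. Chance is argued against for area X. There 1 of 100 splits, the real one, gave as many as 2105 probes, and the highest other gave 1. For the difference between the regions again 1 of 100 did, with a highest other of 47, which argues against chance there too. With 100 splits, a rare split that calls as many cannot be excluded. In VSP the splits decide nothing, since any of the 100 gives at least the real 0 probes; the highest other gave 2. A slide batch is argued against as the whole source in area X, since 1874 probes passed with the slide as a block and 1 of 100 exchanges within slides, the real one, gave as many, with a highest other of 1. Array position as the whole source is argued against for EGR1, which differed by 2.36 among arrays on position 1 alone (limma adjusted p = 0.0383). The exact permutation p there was 0.000777, the smallest possible, with 5 singers against 8 non-singers. With the slide set as a covariate the difference was 2.41 (limma adjusted p = 0.0573). No slide held both groups at position 1, and within slides the singer was always at position 3. Slide and position acting together were therefore not excluded, for EGR1 or the other probes. Array position cannot be told apart from singing for most of the 2105 probes. A total of 34 passed on position 1, 12 of them EGR1 probes, and 2 of 100 splits gave as many. Of these splits, 1 that left all 5 arrays of slide set B on one side gave 1200, which points to the slides. For the 5453 probes of the difference between the regions array position was not tested.

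Probes that differed between singers and non-singers in area X tended to have motif slopes in the same direction, 87.6% of them over the 18 singers. Chance order is argued against, as 1 of 100 orders of the motif numbers, the real one, gave as high a share and the highest other gave 84.4%. Among the 13 singers on position 3, where position cannot act, the share was 67.3% and 12 of 100 orders gave as high a share, so array position may account for part of the relation. The singers with the fewest motifs share position 1 with the non-singers, and a graded response to song stays open as the biological explanation.

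The slides of set B stood apart from those of set A in both regions. The intraclass correlation of the first component between the 2 birds of a slide was 0.984 (permutation p = 1e-05, the smallest that the permutations can give). The sets were defined from this component, so this restates that the slides differ and does not decide for a slide batch. Singing group held 1.47% of the variance of the component between birds (upper bootstrap bound 20.4%), which argues against it. The component had r = 0.0165 with the 75th percentile of signal over 14 slides (bound 0.542). Every array had been scaled to that percentile, so this cannot decide on array brightness. Other measures of the intensity distribution were not tested. Birds were assigned to slides in pairs, so a slide batch and a difference between birds processed together cannot be told apart.

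The comparison of regions also passed its check, with 1 of 100 exchanges of the regions within birds giving as many as 28523 probes; the highest other, 15014, exchanged 6 of the 25 birds and so left most in place.

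The area X array of bird 21, a non-singer outside the final set, had EGR1 at 0.73, while the highest of the 8 non-singers compared was at −1.13. Of 44 sets of non-singer values examined, 4 held a value far from the rest, where chance gives about 1 in 20. D2R in VSP was −1.29 in bird 23 and −2.84 to −2.21 in the other 6 non-singers. EphrinA5 in VSP was −2.62 in bird 18 and −3.29 to −3.05 in the others. LARP5 in VSP was −4.06 in bird 18 and −4.97 to −4.62 in the others. ESR1 in area X was −6.04 in bird 15 and −5.56 to −5.21 in the other 7.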

How the results depend on the processing

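Subsets by slide position, except that of positions 3 and 4 for the motif slope in each region, fits and networks with the slide set and the reading of design names as gene symbols were chosen after the data were seen. Regional difference: of 12 alternatives 11 stayed within 1.5 times of 28523 probes, down to 19330, including 19918 with no replicate block, and normexp gave 18658; without 1 bird it was 28034 to 28543. Among the named genes EGR1 turned to −1.52 in non-singers only and −0.46 at positions 1 and 2, and with normexp ESR1 turned to 0.0696 and Slit3 to 0.10. Of 629 values of named genes between regions, fits without 1 bird included, 607 kept direction and side of the threshold, 15 lost the call, 3 gained it and 4 reversed; with those of EGR1 in the singing and motif comparisons it was 811, 17, 4 and 7 of 839. Singing in area X: of 17 alternatives 12 stayed within 1.5 times of 2105 probes. With normexp 684 passed, for singers with at least 500 motifs 3701, and for singers with fewer 0 by limma (3647 unadjusted). At positions 1 and 2 it was 34, and 1 on the same arrays with the slide set added as a covariate. The subsets had fewer arrays and also differed in position or amount of song, which were not separated. One fit of both regions with bird as a random replicate block gave 2504. Leaving out 1 bird gave 1488 to 2497. EGR1 was 2.25 to 3.12 over its alternatives (adjusted p 8.79e-10 to 0.138). Singing in VSP: 0 probes passed by limma in all 43 fits (643 to 3337 unadjusted), the replicate block and the fits without 1 bird included; EGR1 there turned to −0.13 at positions 1 and 2 and −0.11 with the slide set added. Difference of the singing effect: 1226 passed with normexp, 436 with no replicate block, where the spread between birds enters, and 1114 with the slide by region; without 1 bird 3717 to 6147. Motif slope in area X, main count 1: 0 with normexp (2271 unadjusted), rank (3247), positions 3 and 4 (2518; fewer birds) and age (4037), by limma; 12 with quantile normalization, 53 in the authors' table, 64 with trend and robust variance, 280 with log2, 3023 with all birds, 1048 with the slide as a random block and 74 with the slide set. Without 1 bird it was 0 to 51: 0 for 11 of the 18, 1 without bird 24, 2 without bird 11, 5 without bird 14 or 25, 15 without bird 20, 32 without bird 2 and 51 without bird 5. Motif slope in VSP: 0 in every fit by limma (1159 unadjusted), those without 1 bird included; EGR1 turned to −0.0817 at positions 3 and 4. Difference of motif slopes, main count 0: 2 with quantile normalization, 122 in the authors' table, 16 with trend and robust variance, 823 with log2, and 0 with no replicate block (1067 unadjusted); without 1 bird 0 to 49, with 3 without bird 26, 5 without bird 2, 29 without bird 20, 36 without bird 5 and 49 without bird 14. Acoustic features: 0 in all 88 fits by limma (1207 to 4003 unadjusted as planned). Modules that differed with singing in area X, main count 1: 3 of 15 with quantile normalization, 2 of 7 in the authors' table and 2 of 19 with slide set means removed; in VSP 0 in each network over all arrays, but within slides, where group goes with position, module 1 of the main network passed there. Modules whose r with motifs passed in area X, main count 0: 1 of 5 in the network of singers alone, 2 of 7 in the authors' table and 3 of 19 with slide set means removed; in VSP 0 in each network. No cause was tested for these changes, and fewer birds or arrays are named only as a difference of the fit. Normexp shifted the median of all probes from 0.00 to 0.12 between regions, from 0.03 to −0.10 for singing in VSP and from −0.06 to 0.06 for the difference of the singing effect. The gene lists gave no test under any setting, because none had 5 members among the names found (at most 3, or 4 with design names read as gene symbols), and the named genes have no value in the authors' table, which also gave no region comparison. Dim probes are the limit of signal over background: 3 named genes were tested in no group.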

Other observations

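The test of EGR1 against motifs was chosen after its values had been seen. In area X the level of EGR1 was already high in some birds with little song: of the 6 singers with fewer than 500 motifs EGR1 averaged 0.59 ± 1.38 (SD, n = 6), a spread wider than the 0.45 (SD, n = 12) of the singers with more. One hypothesis is that EGR1 rises with the number of motifs once a bird sings. Pearson's r over the 18 singers was 0.376 (permutation p = 0.124, 95% interval −0.11 to 0.717), so that neither a graded rise nor a level reached with little song can be excluded.

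EGR1 in VSP ranged widely among non-singers, and its mean there was −0.20 ± 0.76 (SD, n = 7), against −1.66 ± 0.38 (SD, n = 8) in area X. The 2 VSP arrays outside the final set had EGR1 at 0.12 and 0.13, within the range of the non-singers compared, whose highest was 0.79. The eigengene of module 2 had an SD of 1.39 among the VSP arrays of non-singers and of 0.85 among those of singers.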
